A study of Mus musculus with 6 samples.

How the data were processed

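The data were 1 table of whole-number counts per Ensembl gene for 6 mouse RNA-seq libraries, 3 in set A and 3 in set B. Per the labels' protocols, blood was drawn, red cells were lysed, basophils were sorted by flow cytometry, and libraries were made with Smart-seq2, a method that amplifies full-length cDNA from very small inputs, and sequenced as paired reads of 150 bases. Smart-seq2 libraries carry no molecular identifiers, so amplified copies count as separate reads, and every interval or floor given for a share covers counting error only. The sample descriptions also name 10x Genomics, and the protocol names Smart-seq2. The table's form, 1 column per library, was read as Smart-seq2.

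The authors deposited raw counts, not normalized, with 1 column per library and no pooling. Per the submitters' processing notes the tools were cutadapt 1.9, HISAT2 2.2.1 and DESeq2, with no role given. The program that counted reads, the genome build, the annotation and the use of strand are not given in the sources used here, so no coordinates are printed. How reads shared between related genes were assigned is likewise not stated, and values of families with near-identical members (granule proteases such as Mcpt8, the alpha globins Hba-a1 and Hba-a2, Rn7s1 and Rn7s2, class I and II histocompatibility genes, ribosomal proteins) are uncertain to that extent. Gene symbols came from a table of Ensembl identifiers, in which 55141 of the 55401 identifiers had a match. The deposited counts summed to 46137963 to 63956911 per library, far above the read yield per sample that the labels state. Low counts were far more often 4 (5211 values) than 3 (819) or 5 (660), and the number of fragments behind a total is not known. A floor of 3 counts corresponded to 0.0469 to 0.0650 CPM.

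CPM values are counts divided by the library's total, on the scale that gives them their name (CPM). The comparison was set B against set A over all 6 libraries with no covariate, by edgeR 4.0.16 in R 4.3.3: filterByExpr by set, TMM scaling, glmQLFit with robust=TRUE, glmQLFTest, and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter left 9196 genes. Standard errors are the absolute log2 fold change divided by the square root of the test's F. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the 33 lists that could be tested, and again with an estimated correlation and with fry. There were 36 lists, 23 of pathways and 13 of other cell types that blood, skin or the gate could hold, with 826 entries of which 12 had no match. A pathway list needed 5 tested members and a cell type list 3. Library measures were compared by 2-sided exact permutation tests.

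The sets, the test, the lists, the rule for named genes and the other settings of the processing were fixed before the data were examined. The rule named genes past the threshold with a mean log2 CPM of at least 4 and no overlap between the sets, up to 4 members past the threshold in each list, 14 genes in any case (Mcpt8, Fcer1a, Ms4a2, Cpa3, Prss34, Il4, Il13, Il6, Adrb1, Il1rl1, Crlf2, Crem, Nr4a1 and 1 that is not reported here) and, since fewer than 10 genes passed, the 10 genes with the smallest p. Other genes named as members of a list, or as genes of the sort gate, were chosen after their values were seen, as those with the smallest p, the highest level or a link to the gate.

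The other settings were RLE scaling, library size alone, no filter, a stricter filter (at least 10 counts in every library of a set and a mean of at least 10 CPM), DESeq2 1.42.0, limma-voom with sample quality weights, robust=FALSE, a replicate block, each library left out in turn, an adjusted p under 0.01, and a log2 fold change of at least 1. Restricting the test to genes with a mean of at least 100, 200, 300 or 500 CPM, dividing counts by 4, library size alone for the lists, and leaving out each library for the totals and shares of counts were added after seeing the data. On simulated counts for the 9196 genes with the spread of these libraries, edgeR called 6% of 50 genes with a planted 4-fold difference, 12% at 32-fold, 30% at 256-fold and 36% at 1024-fold, with 7 calls among 8996 unchanged genes. DESeq2 called 4%, 44%, 70% and 76% of the same genes, with 315 calls among the unchanged. Limma-voom called 0%, 0%, 2% and 0%, with 1 call among the unchanged. Camera called a planted list in 50 of 50 simulations and 3 random lists, with 32 random lists in each simulation. Every member of the planted list was raised by the same large factor and genes were simulated independently. The simulation therefore does not test lists with mixed signs or correlated members. No gene row, library or count was left out beyond the filter.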

Results

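RNA-seq counts were collected from 6 libraries labelled as sorted mouse basophils, rare granulocytes that carry the high-affinity IgE receptor and release histamine, proteases and cytokines. The 3 libraries of set A had almost no counts of Fcer1a, the IgE-binding chain of that receptor (4, 0 and 0). Differences between the sets are therefore not read here as changes within basophils. The mice were taken from a model of atopic dermatitis in which MC903, a vitamin D analogue, is put on the skin of both ears each day. The dose was 2 nmol in 10 µL of ethanol from day 0 to day 6, and control mice received ethanol alone. The libraries form 2 sets of 3, named A and B in the labels. Which set received MC903 is not given in the sources used here, so every difference is stated as set B relative to set A. The sort gate took live CD45+ cells that lacked lineage markers and carried CD49b with FcεRIα or surface IgE. The library labels name blood as the tissue and the design text names ear skin, and this was not resolved here. Nothing in the labels says whether the 3 libraries of a set came from separate animals or pools, so p-values measure only the spread between these libraries, which may be technical.

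Total counts in set A were 55116567, 52863758 and 46137963 for replicates 1, 2 and 3, and those in set B were 49742321, 59129866 and 63956911. No difference between the sets was detected in the totals (exact permutation p = 0.3) or in the number of genes with at least 1 count (10123 ± 1047 in A, 12461 ± 1483 in B, SD, n = 3 each, exact permutation p = 0.2). Each exact test of 3 libraries against 3 was 2-sided and could not go below p = 0.1. The share of counts from mitochondrially encoded genes was 2.81% ± 0.931 in A and 1.84% ± 0.116 in B (SD, n = 3, exact permutation p = 0.1, Benjamini-Hochberg adjusted p = 0.35 over the 7 library measures tested). The difference of -0.965 percentage points was -0.429 without A replicate 2. Haemoglobin transcripts took 0.0481% ± 0.0188 of counts in A and 0.0142% ± 0.00355 in B (SD, n = 3, exact permutation p = 0.1, adjusted p = 0.35). Ribosomal protein genes took 2.46% ± 0.292 in A and 2.31% ± 0.277 in B (SD, n = 3, exact permutation p = 0.6). The 20 most abundant genes took 19.3% ± 1.12 and 17.0% ± 1.81 (SD, n = 3, exact permutation p = 0.3).

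The comparison of set B with set A asks which transcripts differ between the libraries of the sets, and the series title places it in a study of sympathetic nerves acting on basophils. Mcpt8 (ENSMUSG00000022157), a serine protease stored in mouse basophil granules, was at 841 ± 349 CPM (counts scaled by the library's total) in B and 0.907 ± 0.324 CPM in A (SD, n = 3 each). Prss34 (ENSMUSG00000056399), a second basophil granule protease, was at 584 ± 236 CPM in B and 0.596 ± 0.264 CPM in A (SD, n = 3 each). Both rose in B in 3 of 3 libraries, Mcpt8 by 9.76 on the log2 scale (SE 0.58, adjusted p = 0.0125 by edgeR's quasi-likelihood test) and Prss34 by 9.84 (SE 0.67, adjusted p = 0.0155). Carry-over of reads between libraries stays open as the source of their few counts in A, so both differences may be lower bounds. Mcpt8 and Prss34 were the 2 genes past the threshold among 9196 tested, and 0 genes were lower in B. At an unadjusted p under 0.05 edgeR counted 464 genes higher in B and 121 lower. DESeq2 called 1112 genes higher and 102 lower, and limma-voom called 195 higher and 7 lower with neither Mcpt8 nor Prss34 among them. On simulated counts limma-voom called at most 2% of the genes with a planted difference, at each of the 4 sizes tried, and 1 of 8996 unchanged genes. It called 202 genes on the real counts, so the simulation may not reflect its power on these libraries. Without any one of A replicates 1, 2 and 3 or B replicates 1 and 2 edgeR called 0 genes (695 to 1030 at an unadjusted p under 0.05), and without B replicate 3 it called Mcpt8 alone. With a replicate block edgeR also called 0 genes. Mcpt8 was then 9.72 and Prss34 9.86 higher in B on the log2 scale (adjusted p = 0.194 for both).

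Among the 22 tested members of the basophil identity list, 2 rose (Mcpt8 and Prss34) and 20 did not pass over all genes tested by edgeR. DESeq2 also called Cpa3 (adjusted p = 2.45e-06) and Fcer1a (adjusted p = 3.94e-05), and limma-voom called Fcer1a (adjusted p = 0.0374). Adjusted over the list alone, 6 members, Mcpt8 and Prss34 among them, were higher in B by edgeR and 0 were lower. The other 4 were Ifitm1, an interferon-inducible membrane protein (115 ± 50.7 CPM in A, 865 ± 140 in B), Cpa3, a granule carboxypeptidase (0.118 ± 0.0407 in A, 81.9 ± 44.8 in B), Fcer1a (0.0242 ± 0.0419 in A, 117 ± 89.2 in B), and Cd200r3, an activating receptor of basophils (0.0652 ± 0.0575 in A, 68.5 ± 54.8 in B; SD, n = 3 for each). In raw counts Fcer1a had 4, 0 and 0 in A and 10736, 5584 and 2681 in B. Fcer1g, the signalling chain that many myeloid cells share, was at 5445 ± 105 CPM in A and 5448 ± 1572 in B. Itga2, which encodes the CD49b of the gate, was at 0 CPM in all 3 A libraries and at 13.99, 31.91 and 0 CPM in B. A floor of 3 counts corresponds to 0.0469 to 0.0603 CPM in B and 0.0544 to 0.0650 CPM in A. Ptprc, which encodes CD45, was at 740 ± 167 CPM in A and 573 ± 47.7 in B (SD, n = 3). Camera placed the list higher in B (adjusted p = 0.0179), and adjusted p = 0.500 with an estimated correlation. Its members did not move as 1 block: 12 fitted values lay above 0 and 10 below, with a median log2 fold change of 0.38. That median was 1.33, 2.61 and 1.09 without A replicate 1, 2 and 3, and 0.595, 0.155 and 1.63 without B replicate 1, 2 and 3. It was 1.98 with no filter, 1.30 with a replicate block and 0.21 with RLE scaling.

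**Figure D1:**
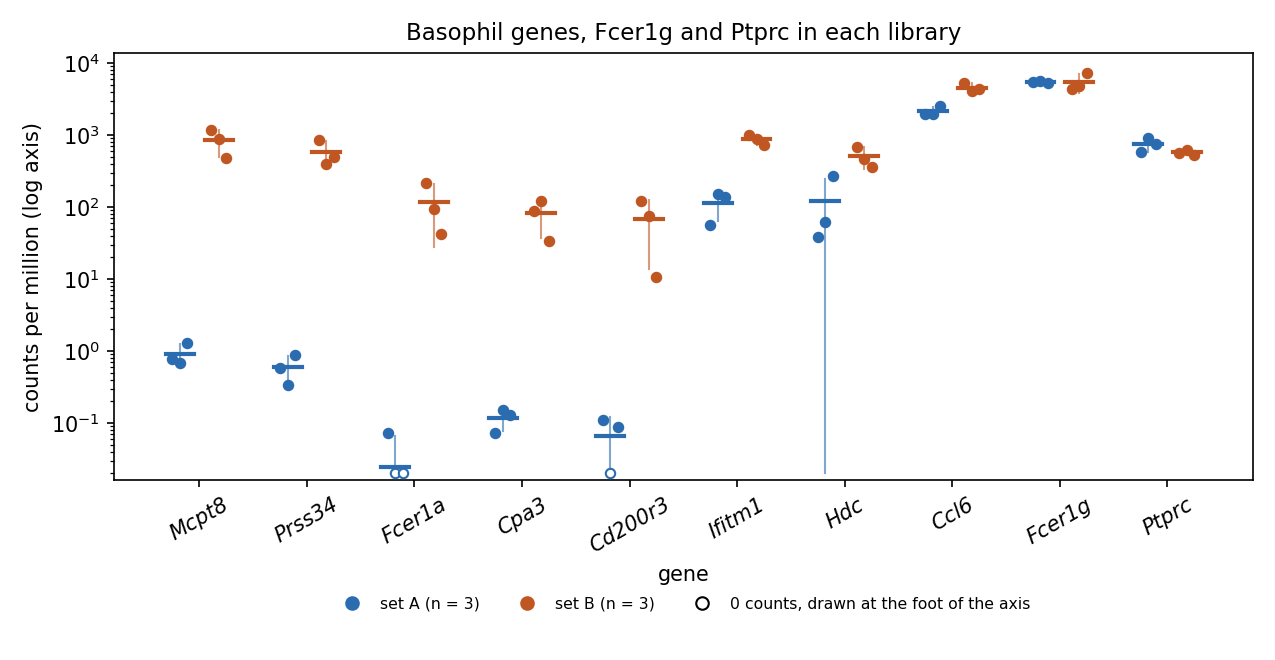
CPM of 8 basophil genes, Fcer1g and Ptprc in each library on a log axis, with 1 point per library, a horizontal bar for the mean and a vertical line for 1 SD on each side (n = 3 per set), which stops at the foot of the axis where the mean minus the SD lies under it. Mcpt8 lay between 478 and 1173 CPM in the 3 B libraries and between 0.681 and 1.28 CPM in the 3 A libraries, while the ranges of the sets overlapped for Fcer1g and for Ptprc. All 8 basophil genes drawn had higher means in B, but some of them were chosen after their values were seen. Ccl6 stands in the list of cytokines and mediators and not in the identity list, and Hdc also stands in the neutrophil list. Of the 22 tested members of the basophil identity list, 10 had a fitted value below 0, and 0 of these had an unadjusted p under 0.05 by edgeR.

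Basophil cytokines and mediators were also placed higher in B by camera (adjusted p = 0.00699, and adjusted p = 0.449 with an estimated correlation). Of the 19 members tested, 2 rose by edgeR, the same Mcpt8 and Prss34, and 17 did not pass. The list shares 4 genes with basophil identity, Mcpt8, Prss34, Cpa3 and Hdc, so the calls of these lists are not independent. Mcpt8, Prss34 and Cpa3 passed in both when each list was adjusted alone. Adjusted over the list alone 6 were higher in B and 0 lower, and these included the chemokine Ccl6 (2126 ± 312 CPM in A, 4545 ± 658 in B), Tnfsf13b, the B cell survival factor BAFF (0.0378 ± 0.0655 in A, 47.5 ± 5.48 in B), and Hgf, which was at 0 in all 3 A libraries and at 18.9 ± 16.5 CPM in B (SD, n = 3 each). Against the floor of 3 counts per library Hgf was at least 8.33 higher in B on the log2 scale, a bound that would be 2 lower if each read pair added 4 to a count. The list's median log2 fold change was 1.00 (0.411 without B replicate 2, 2.08 with no filter), and it stayed at 1.00 with Hgf set at that bound. Il13 had 0 counts in all 6 libraries, Il4 had 535 counts (10.8 CPM) in B replicate 1 and 0 in the other 5, and Il6 had 4 counts in each of B replicates 2 and 3 and 0 elsewhere.

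The neutrophil list was placed higher in B (camera adjusted p = 0.00249, and adjusted p = 0.587 with an estimated correlation). All 13 of its tested members had a fitted value above 0, with a median of 1.55 on the log2 scale, and 0 of the 13 passed over all genes tested. Adjusted over the list alone 3 were higher in B and 0 lower: Retnlg, a secreted resistin family protein (548 ± 156 CPM in A, 1704 ± 207 in B), and the granule proteins Ngp (1.70 ± 0.420 in A, 140 ± 164 in B) and Camp (0.613 ± 0.0511 in A, 70.2 ± 35.0 in B; SD, n = 3 each). S100a8, an abundant calcium-binding protein of neutrophils, was at 1259, 4455 and 5378 CPM in A and 13750, 7357 and 7251 CPM in B. Hdc, the histamine-forming enzyme, stands in this list and in both basophil lists, and was at 122 ± 126 CPM in A and 504 ± 166 in B (SD, n = 3).

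Lists placed lower in B were T cells, erythroid cells and the interferon gamma response. Of the 11 T cell genes tested, 10 had a fitted value below 0 and 0 passed, with a median log2 fold change of -1.13 (camera adjusted p = 0.00699, and adjusted p = 0.449 with an estimated correlation). Trac, the constant chain of the alpha T cell receptor, was at 154 ± 83.3 CPM in A and 25.1 ± 12.6 in B, and Cd8b1, a chain of the CD8 coreceptor, was at 172 ± 113 and 3.69 ± 5.82 (SD, n = 3 each). All 6 tested erythroid genes had a fitted value below 0 with a median of -2.24, and 0 passed (camera adjusted p = 0.0212, and adjusted p = 0.449 with an estimated correlation). Hba-a1, an alpha globin, was at 277 ± 71.2 CPM in A and 104 ± 42.2 in B (SD, n = 3). The interferon gamma response had 15 of 22 fitted values below 0 with a median of -0.52 (-0.107 without A replicate 1), and 0 members passed (camera adjusted p = 0.0445, and adjusted p = 0.587 with an estimated correlation). Its members with the smallest p were the class II genes H2-Aa (2227 ± 444 CPM in A, 1239 ± 242 in B) and H2-Eb1 (1127 ± 379 in A, 479 ± 173 in B) and the class I gene H2-K1 (2936 ± 334 in A, 2092 ± 314 in B; SD, n = 3 each). Adjusted over the list alone, 0 members of these 3 lists passed. At an unadjusted p under 0.05 edgeR counted 2 T cell genes, 1 erythroid gene and 5 interferon gamma genes, each lower in B. Of the 6 list calls, 0 remained without A replicate 1, 3 without A replicate 2 and 4 without A replicate 3. Without B replicate 1 the T cell call alone remained, and 5 remained without B replicate 2 and 4 without B replicate 3. The interferon gamma call remained in 1 of the 6 omissions, that of A replicate 3. It also ended with library size alone (adjusted p = 0.0595, median -0.39), with a replicate block (adjusted p = 0.0742) and by fry (adjusted p = 0.314), and over all its settings the adjusted p ran from 0.0202 to 0.587. By fry the T cell call ended as well (adjusted p = 0.0624, with 0.000753 to 0.449 over all settings).

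**Figure D2:**
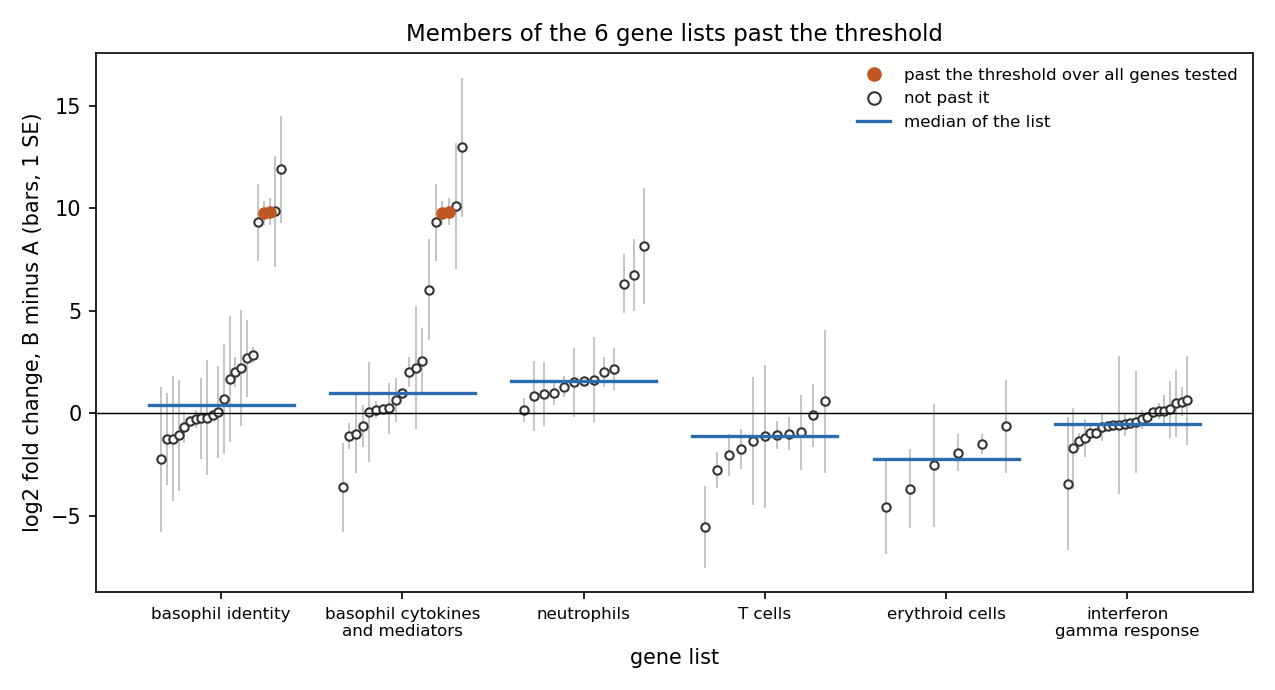
Log2 fold change (B minus A) of every tested member of the 6 gene lists past the threshold by camera, with bars of 1 SE and a line at each list's median. Filled points are the 2 genes past the threshold over all genes tested, Mcpt8 and Prss34, which stand in both basophil lists, and the neutrophil members lie above 0 while the erythroid members lie below it.

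**Figure D3:**
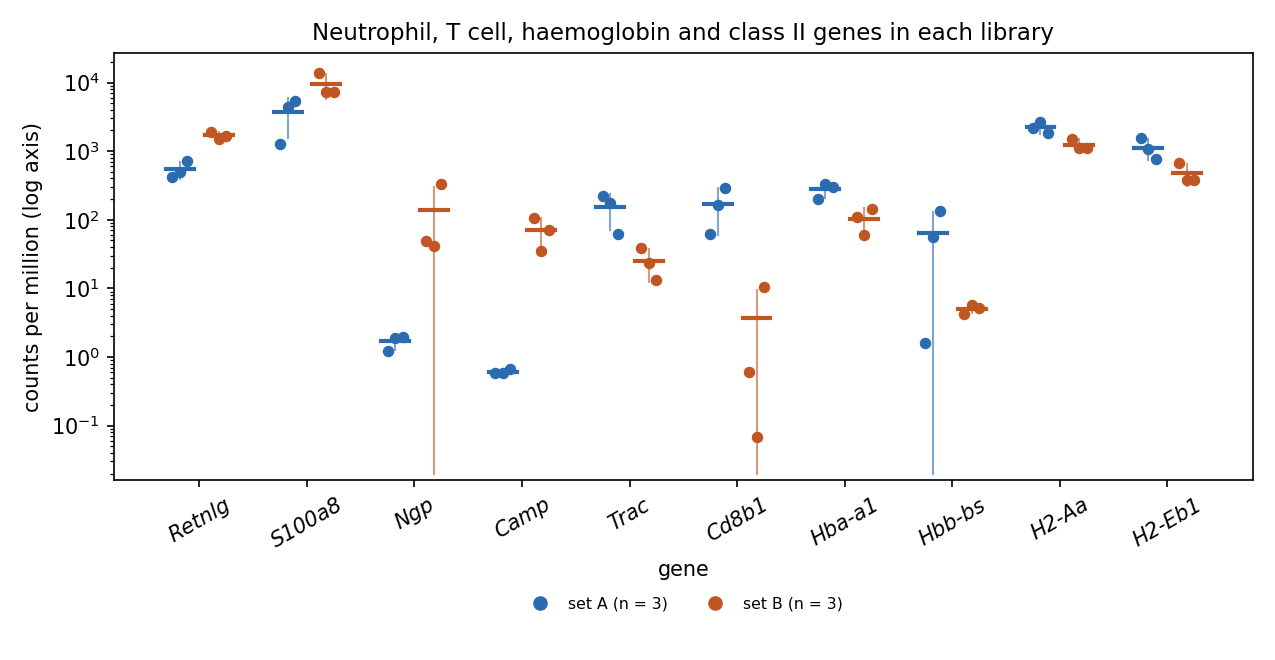
CPM of neutrophil genes (Retnlg, S100a8, Ngp, Camp), T cell genes (Trac, Cd8b1), globins (Hba-a1, Hbb-bs) and class II genes (H2-Aa, H2-Eb1) in each library on a log axis, with 1 point per library, a horizontal bar for the mean and a vertical line for 1 SD on each side (n = 3 per set), stopped at the foot of the axis where it would go below. Retnlg lay between 422 and 723 CPM in A and between 1523 and 1930 CPM in B.

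Receptors for transmitters of nerves were read out because the series title concerns sympathetic input. Adrb1, the beta-1 adrenergic receptor, had 50 counts in A replicate 3, 4 in B replicate 2 and 961 in B replicate 3, and 0 in the other 3 libraries, and was not tested. Of the neurotransmitter and neuropeptide receptors, 5 of 32 could be tested and 0 passed. Adjusted over the list alone 1 was higher in B, the adenosine receptor Adora2b (0 to 0.113 CPM in A, and 176, 78.2 and 11.04 CPM in B). The list that joins targets of cyclic AMP with the machinery of its pathway, such as subunits of protein kinase A and arrestins, gave no call (17 tested, median -0.07, camera adjusted p = 0.967). Nr4a1, an immediate early gene, was at 861 ± 229 CPM in A and 768 ± 102 in B (log2 difference -0.26, SE 0.24, adjusted p = 1.00 by edgeR). Crem was at 55.8 CPM in B replicate 1, 7.22 in B replicate 3 and under 0.2 in the other 4 libraries.

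Receptors through which alarmins act on basophils showed no call. Il1rl1, the IL-33 receptor, had 0 counts in all 6 libraries, and Crlf2, the TSLP receptor, was at 54.3 ± 13.2 CPM in A and 49.0 ± 23.7 in B (SD, n = 3, log2 difference -0.23, SE 1.13, adjusted p = 1.00 by edgeR). Ms4a2, the beta chain of the IgE receptor, had 0, 629 and 0 counts in A and 949, 1226 and 65 in B, with a log2 difference of 1.67 (SE 3.08, adjusted p = 1.00 by edgeR). That difference was 12.49 without A replicate 2, 1.07 without A replicate 1 and 1.09 without A replicate 3, and it was 7.86 with a replicate block and 5.71 by limma-voom. Of 15 cytokine and alarmin receptors and 23 genes of Fc epsilon receptor signalling tested, 0 passed by edgeR, and 1 receptor was higher adjusted over the list alone, Il5ra. Its level was low, at 0 in all A libraries and at 3.80, 1.93 and 1.53 CPM in B replicates 1, 2 and 3 (adjusted p = 0.508 over all genes tested by edgeR). Fcer1a, of the second list, passed by DESeq2 (adjusted p = 3.94e-05) and by limma-voom (adjusted p = 0.0374).

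Beyond Mcpt8 and Prss34, the genes with the smallest p did not pass in the main edgeR fit. Ly6a came next (262 ± 43.2 CPM in B, 0.944 ± 0.498 in A, adjusted p = 0.0634 by edgeR), and Ifitm1, Retnlg, Ccdc92, Ccl6, Mfap3, Pex19 and Sumo3 followed, each with an adjusted p of 0.508. Ccdc92 was the only one of these with its higher values in A (103 ± 24.2 CPM in A, 0.173 ± 0.0137 in B), while Mfap3, Pex19 and Sumo3 averaged 133, 120 and 110 CPM in B and under 0.3 CPM in A. Ly6a passed with the stricter filter (adjusted p = 0.0416 by edgeR). DESeq2 called Ly6a, Ccdc92, Mfap3, Pex19 and Sumo3, and limma-voom called Ccdc92 and Sumo3. Values near 0 in single libraries were common at low abundance. Among tested genes with a mean between 10 and 100 CPM, 28.0% of the library values were under 1 CPM, against 0.0817% among genes with a mean of 300 to 1000 CPM. Of the tested genes, 1294 (14.1%) had no overlap between the sets, where chance gives 10%.

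The other 27 lists tested gave no call, with adjusted p from 0.0605 to 0.967 by camera, and in 14 of them the median, the mean and the direction of the test did not share a sign. Library size alone as the scaling turned the median of 5 of them from below to above 0. Among other cell types, the median log2 fold change was -0.75 for platelets (adjusted p = 0.112), -0.61 for NK cells (adjusted p = 0.293), -0.64 for dendritic cells (adjusted p = 0.347), -0.19 for B cells (adjusted p = 0.376), 0.26 for monocytes and macrophages (adjusted p = 0.677), 0.01 for fibroblasts and endothelium (adjusted p = 0.852) and -0.78 for eosinophils (adjusted p = 0.967). H2-Aa in the dendritic cell list and Il5ra in the eosinophil list passed when adjusted over the list alone, the first lower and the second higher in B. Il5ra averaged only 2.42 CPM in B. Mast cells and ILC2 had 2 tested members each and keratinocytes had 0, so these 3 lists were not tested, and 9 of the 12 matched keratinocyte genes had 0 counts in every library. Kit, the mast cell growth factor receptor, had 0 counts in all 6 libraries.

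Ribosomal proteins came closest among the pathway lists (median -0.08, adjusted p = 0.0605; the median was 0.01 with library size alone), followed by mitochondrially encoded genes (median -0.52, adjusted p = 0.0772). In the latter mt-Rnr2, mt-Rnr1 and mt-Nd1 were lower in B when adjusted over the list alone. Immediate early genes had a median of -0.39 (adjusted p = 0.297), NF-kB targets -0.16 (adjusted p = 0.347), heat shock proteins 0.21 (adjusted p = 0.347, and 0.00216 by fry), STAT5 targets -0.47 (adjusted p = 0.574), cytokine and alarmin receptors -0.47 (adjusted p = 0.657) and neurotransmitter and neuropeptide receptors 0.30 (adjusted p = 0.460). Medians were 0.22 for cell cycle and 0.11 for oxidative phosphorylation (adjusted p = 0.507 for both), -0.13 for the unfolded protein response (adjusted p = 0.468) and -0.02 for glycolysis and hypoxia (adjusted p = 0.852). They were -0.15 for the vitamin D response, the pathway that MC903 activates (7 tested, adjusted p = 0.852), 0.44 for the glucocorticoid response and -0.18 for apoptosis (adjusted p = 0.928 for both), and 0.44 for the type I interferon response (adjusted p = 0.954). Lipid mediators with cholesterol synthesis had a median of -0.20, migration and adhesion -0.14 (adjusted p = 0.711 for both), and Fc epsilon receptor signalling -0.00497 (adjusted p = 0.924). Adjusted over the list alone, Camp in the vitamin D response and Isg20 in the type I interferon response (0.191 ± 0.0620 CPM in A, 97.6 ± 24.98 in B, SD, n = 3) were higher in B. Camp is the granule gene reported above in the neutrophil list, so it is not read here as a sign of vitamin D action.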

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

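The restriction to genes above a mean CPM, the division of counts by 4, the lists with library size alone and the omissions for totals and shares of counts were chosen after seeing the data. The count of 2 genes, both higher in B, was found again with RLE, library size alone, no filter, robust=FALSE, counts divided by 4 and a log2 fold change of at least 1, and the stricter filter gave 3, these 2 and Ly6a. DESeq2 called 1214 genes, these 2 among them, and limma-voom called 202, with 0 of these 2 among them. The replicate block gave 0 calls (345 at an unadjusted p under 0.05), as did an adjusted p under 0.01. Leaving out 1 library at a time gave 0 to 1 calls. The restriction to a mean of at least 100, 200, 300 or 500 CPM gave 3, 9, 12 and 9 calls, with 2, 2, 1 and 0 of the 2 genes among them, where fewer genes and a smaller spread were tested. Prss34 lay below the limit of 300 and both genes below that of 500, so they were not tested there. The causes of the other shifts were not tested. Mcpt8 and Prss34 stayed between 9.42 and 10.14 on the log2 scale over the omissions, with adjusted p from 0.0322 to 0.285. These sizes may be lower bounds, since carry-over between libraries stays open as the source of the counts in A.

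Of the lists, 6 passed by camera, 0 with the correlation estimated, 6 by fry (4 shared), 7 with RLE, 9 with no filter, 5 with library size alone and 5 with the replicate block. The 6 were all among those with RLE and with no filter, and 5 of them among those of the last 2 settings. Fry added heat shock proteins (adjusted p = 0.00216) and eosinophils (adjusted p = 0.0380). RLE added ribosomal proteins, and no filter added ribosomal proteins, mitochondrially encoded genes and platelets. Omissions gave 0 to 5 lists, with 0 without A replicate 1, 3 without A replicate 2 and 2 without B replicate 1, where 1 of the 6 remained and ribosomal proteins came in. No median of the 6 lists changed sign in these settings, but over the omissions that of basophil identity ran from 0.155 to 2.61, that of mediators from 0.411 to 1.29 and that of the interferon gamma response from -0.608 to -0.107. The log2 difference of Crlf2 ran from -0.574 to 0.0827 over the omissions, so its sign changed when 1 library was left out. No pairing by replicate number was detected: deviations of same-numbered libraries correlated at 0.0280, -0.0241 and 0.0261, and only A replicate 1 correlated best with its own number. With so few libraries and so wide a spread this cannot exclude a pairing by animal, sort or batch. Scaling by RLE shifted the median of all genes to -0.16 and library size alone to 0.05, against -0.06 with TMM. The spread was wider at low abundance: the median coefficient of biological variation was 1.75 for genes with a mean of 10 to 100 CPM and 0.514 at 300 to 1000 CPM. What limits detection here was not tested.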

Other observations

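The tests of abundant genes, of dropout, of other cell types, of carry-over, of detection, of low counts and of splits for DESeq2 were chosen after the results were seen, while the splits for the edgeR and camera counts were planned. Among the 525 genes with a mean of at least 300 CPM, edgeR called 12, of which 5 were higher in B (Mcpt8, Ifitm1, Retnlg, Lrg1, Ccl6) and 7 lower (CT010467.1, mt-Rnr1, mt-Rnr2, Rn7s1, Rn7s2, Tsc22d1, Degs1). Non-coding structural RNAs made up most of the lower group. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 fell by 0.88 and 1.40 on the log2 scale (SE 0.18 and 0.28, both adjusted p = 0.0126), Rn7s1, an RNA of the signal recognition particle, fell by 1.55 (SE 0.35, adjusted p = 0.0213), and CT010467.1 fell by 1.21 (SE 0.23, adjusted p = 0.00914). Together with Rn7s2 these took 2.95% ± 0.590 of counts in A and 1.41% ± 0.242 in B (SD, n = 3). The secreted glycoprotein Lrg1, made by neutrophils and liver, rose from 209 ± 97.2 to 823 ± 133 CPM (log2 1.93, SE 0.40, adjusted p = 0.0126). RLE scaling left 11 of these calls and library size alone 10, with 5 higher in B in both. Calls numbered 3 without B replicate 2, 6 without B replicate 1, 7 without B replicate 3 and 8 without A replicate 1, and 14 without A replicate 2 or A replicate 3.

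In every library the most abundant transcript was Lyz2, the lysozyme of monocytes, macrophages and neutrophils, at 22600 to 39756 CPM, 19.3 to 62.2 times the level of Mcpt8 in the B libraries. Immunoglobulin and B cell genes were high throughout, with Igkc at 1523 to 2807 CPM and Cd79a at 569 to 1284 CPM. The NK and T cell granule gene Nkg7 was at 468 to 1278 CPM and the platelet chemokine Ppbp at 151 to 627 CPM. Which of these cell types a gate without lineage-positive cells would remove depends on its markers, which are not listed here.

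The first pattern is the near absence from the A libraries of transcripts of Mcpt8, Prss34, Fcer1a, Cpa3 and Cd200r3. It does not hold for the whole basophil identity list, where 12 fitted values lay above 0 and 10 below. At an unadjusted p under 0.05 edgeR counted 7 members higher in B and 0 lower. Of 9 tested members averaging at least 100 CPM, 4 had all B values above all A values, 0 had the reverse and the rest overlapped. Among the members below 0, Gata2 was at 53.9 ± 58.3 CPM in A and 22.9 ± 20.9 in B (SD, n = 3, log2 difference -1.25, SE 2.24). For Mcpt8 and Prss34 loss of single transcripts at low input is argued against only weakly. Of 273 other genes at 400 CPM or more in every B library 0% were under 1% of their B mean in all A libraries (a count of 0 allows up to 1.10%). These genes include far more abundant ones such as Lyz2, and the level lies just under the lowest B value of Prss34 (401 CPM). Genes averaging 200 to 400 CPM in B, such as Ly6a (262 CPM in B, 0.944 in A, outside the basophil lists), were not examined for such loss. For Cpa3, Fcer1a and Cd200r3, each taken alone, such loss stays open. Of 2155 other genes averaging 50 to 200 CPM in B, with at least 10 CPM in every B library, 59 (2.74%) were as low in A. Of the basophil identity genes at that level, on a list fixed before the data were examined, 3 of 4 were as low. For these 3 as a set, that argues against loss at the rate of other genes. It rests on 4 genes and on a level chosen after the results were seen. Carry-over between libraries stays open for the few basophil counts in A, since the range that held 15 of 15 cases begins at 0 and comes from genes chosen for low counts. RNA of other blood cells was present in all libraries, since at least 3 of 6 lists of other blood cells had 3 or more markers at 100 CPM or more in each, and 6 of 6 did in each A library. It may be that the A libraries hold few basophils, and the B libraries are not read here as basophils alone. B cell markers at 100 CPM or more numbered 11, 9 and 8 of 12 in A replicates 1, 2 and 3, and 7, 8 and 7 in those of B. Whether the treatment, the sort or a label separates the sets stays open and was not tested, because the labels do not say which set was treated.

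The second pattern is the 1214 calls of DESeq2 against 2 of edgeR. Of the 1112 called higher in B, 98.4% were under 1 CPM in all A libraries, and 767 were also under 1 CPM in at least 1 B library. Independent dropout in libraries of unequal complexity is a candidate explanation that the test leaves open: genes detected in exactly 3 libraries were detected in the 3 B libraries 1.08 times as often as the detection odds of single libraries predict (95% Poisson interval 0.954 to 1.23), but 100 such genes added to simulated libraries gave 1.19, inside that interval, and the 767 lie outside this group of genes. On simulated counts DESeq2 called 315 of 8996 genes without a planted difference, so false calls are another candidate for part of the 1214. On the 7803 genes with a mean of at least 10 CPM the real split gave DESeq2 635 calls. The other 9 splits, each of which mixed A and B libraries, gave 263 to 582. Of the 10 splits 1, the real one, was as large, and 10 splits are too few for a share under 0.05.

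The third pattern is an excess of counts that are multiples of 4. Over all libraries counts of 4, 8 and 12 were 2.98, 1.59 and 1.24 times as frequent as the mean of the even counts on either side. Counting each read pair as 2, with no other step, is argued against, since it gives no excess of 4 over 2 and 6, and the factor at 4 was 1.92 to 3.48 in the 6 libraries. Counting each pair as 4 stays open, since the factor at 12 was 1.24, close to the neighbours, and lower counts were present. Dividing the counts by 4 left 2 genes called.

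For the 2 genes called by edgeR, 1 of the 10 splits of the 6 libraries gave as many, the real one, and the highest of the others gave 0. For the 6 lists called by camera, 1 of the 10 splits gave as many, the real one, and the highest of the others gave 0. In both cases 10 splits are too few for a share under 0.05.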
